A study of Mus musculus with 6 samples.

How the data were processed

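RNA from mouse liver was measured on an Illumina bead array, which reads the brightness of fluorescently stained, biotin-labelled copies of the RNA bound to beads that each carry 1 probe. Per the labels, C57Bl/6N mice aged 8 weeks received an intraperitoneal injection of tunicamycin at 2.5 mg/kg or of vehicle, and liver was taken after 12 hours. The 6 arrays fall into 3 vehicle and 3 tunicamycin samples by their titles. The titles number the replicates, and nothing in the sources used here ties a number to a litter, chip or day, so the numbers served as names. Sex, chip and scan batch are not given in the sources used here. Where replicates share a source not stated, the p-values measure only the spread between these arrays.

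The deposited table of mean bead intensity, per the file headers an average signal for each probe, held 45281 probes per array. Its values were neither background-subtracted nor normalized between arrays, which was read from the values, since the medians differed and the lowest value of each array lay far above 0. The deposited detection p-value of each probe, per the file headers, stands beside each signal column. The 6 detection columns share 1 name, and each was taken from the column to the right of its array's signal, with which it ranked most closely for 6 of 6 arrays. A second deposited table held intensity values of the same arrays. From the values, these were background-subtracted, on a linear scale and quantile-normalized, as 99.97% of the ranked values lay within 0.1 of each other across the arrays and the lowest values were below 0. Each of its 6 columns ranked most closely with its own array. The scanner and the software are not given in the sources used here, and the second table served only as an alternative.

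The analysis started from the mean bead intensity. In limma 3.58.1 on R 4.3.3, background was corrected by normexp with the background inferred from the detection p-values, an offset of 16 was added, and the arrays were quantile-normalized and put on the log2 scale. A fold change on this scale understates the change of dim genes because of the offset. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, which left 16559 probes. Gene names came from the platform annotation, set against a table of mouse genes from the GRCm38.p6 assembly by Entrez ID. There were 34885 probes with 1 gene symbol, 18 with several and 10378 without a name here. Of the named probes, 78 had no entry in the mouse table, and 0 symbols needed an update. No coordinates are printed, as no build is named. Each gene was represented by its probe with the highest mean over all arrays, and unnamed probes were kept as separate items, giving 11678 items tested, of which 9332 were named genes. Among 3406 items with several kept probes, probes of 48 were called in opposite directions, and 1016 had both called and uncalled probes. Probes for members of families with similar sequences, such as the Cyp2c, Mup, Ces1, Saa and globin genes, can bind more than 1 transcript, so their values are uncertain for a single gene.

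Tunicamycin was compared with vehicle by limma's moderated test (lmFit and eBayes) with Benjamini-Hochberg adjustment over the items tested and a threshold of 0.05. Every adjusted p for a gene comes from this test and is two-sided. Errors of log2 fold changes are standard errors from the same model, and errors of group means are standard deviations over 3 arrays. The number of arrays limits the precision. A gene whose probe had a detection p of 0.05 or more on every array of a group was not well above background there. For such a gene the fold is given as "at least N-fold", with the dim group set, per array, to the higher of the probe's own value and the lowest value among detected probes.

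Genes named in the text follow a rule fixed before the data were examined. It takes 13 index genes, whatever their result, then the 10 largest rises and the 10 largest falls among named genes past the threshold whose 3 arrays of 1 group all lay above those of the other. It also takes up to 3 members with the largest called change from each gene list, or the member with the smallest p where no member passed. Other genes named in the text are members of those lists, chosen after their values were seen. Of the 52 genes chosen for the text that had several tested probes, 29 had probes whose fold changes differed by more than a factor of 1.5, and in 22 of these all probes were called in the same direction. The text gives the brightest probe, so the sizes for such genes, among them Acss2, Bdh1, Casp9, Ifit3, Srprb and Serpina7, depend on this choice. The 43 gene lists for pathways and cell types were written from general knowledge before the data were examined, and the 41 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera asks whether the genes of a list rank higher or lower than the other genes. It was repeated with the correlation estimated for each list, and with fry, which asks whether the genes of a list move on balance in 1 direction. A further 5 lists were written after the results were seen.

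The gene test and the list test were tried on simulated values before use. Background correction, normalization and the detection filter were not part of the simulation. In a simulated comparison of tunicamycin with vehicle over 11678 genes, 200 were changed. At log2 changes of 0.5, 1 and 2 the test recovered 22.7%, 86.6% and 98.5% of the changed genes, and it called 10 of 11478 unchanged genes. In the simulated lists, 5 of 5 shifted lists were recovered with 0 false calls. The simulated genes varied independently of each other, and a smaller share was changed than in the data. The simulation therefore does not show how camera behaves where the genes of a list are correlated. In the data the estimated correlation reached 0.721, in the macrophage list. Alternatives were no background correction, other normalizations, the second deposited table, other filters on dim probes, other ways to treat several probes of a gene, other settings of the model, the replicate number as a block, and leaving out each array in turn. Figures were drawn with matplotlib. Every column of sample values was used.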

Results

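The series measured RNA in mouse liver 12 hours after tunicamycin or vehicle, with 3 arrays per group. Tunicamycin blocks the first step of N-linked glycosylation, so that unfolded glycoproteins build up in the endoplasmic reticulum (ER) and set off the unfolded protein response. The comparison asks which liver transcripts differ after this challenge. Between 15503 and 16603 of the 45281 probes had a detection p under 0.05 on an array, and the median raw signal of the arrays ranged from 88.9 to 96.8. Over the kept probes, arrays of the same group correlated at r = 0.989 to 0.994 and arrays of different groups at r = 0.887 to 0.901, across probes, which are not independent replicates. The first principal component held 91.3% of the variance and separated the groups.

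Tunicamycin changed most of the liver transcripts that passed the detection filter, in both directions. Of 11678 items tested, 3621 rose and 3670 fell, which is 62.4% of them. Without the detection filter, 23.3% of 29453 items changed. At least 2-fold, 1288 rose and 1348 fell. The 3 arrays of one group lay wholly above those of the other for 7785 items, or 66.7%, where chance gives 10%. The median log2 fold change of all items was -0.0081. Quantile normalization gives all arrays the same distribution, so this median and the balance of rises and falls are partly set by the processing. Of the genes that rose, 191 were not well above background on any vehicle array, and 248 of those that fell were not on any tunicamycin array.

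Ddit3 and Atf3, which encode stress transcription factors, had the 2 largest rises among the index genes. Ddit3, which encodes the transcription factor CHOP, went from a normalized log2 intensity of 5.70 ± 0.08 to 13.81 ± 0.09 (SD, n = 3), a 276-fold rise (adjusted p = 4.10e-11). Atf3 rose 66.4-fold, with a log2 fold change of 6.05 ± 0.23 (SE), and Trib3, an ATF4 and CHOP target, rose 28.8-fold. Fgf21, a hormone secreted by the liver, rose 38.2-fold, and Atf4 rose 3.69-fold. Among ER genes, Dnajb9 rose 12.4-fold, Herpud1 2.38-fold, and Dpagt1, the enzyme that tunicamycin inhibits, 2.42-fold with a log2 fold change of 1.27 ± 0.10. Hspa5, the chaperone BiP, rose 4.80-fold, but its only tested probe was dim and detected on 1 of 3 vehicle arrays. Xbp1 rose by 0.37 ± 0.11 on the log2 scale (adjusted p = 0.0134). Splicing of Xbp1 was not analysed here.

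Cebpa, a transcription factor of differentiated hepatocytes, fell 5.17-fold (log2 fold change -2.37 ± 0.12). Hnf4a, another such factor, had a log2 fold change of -0.31 ± 0.11 (adjusted p = 0.0329). The call of Xbp1 ended in 2 of 17 alternative settings, with 1 median per array and without vehicle replicate 3, and that of Hnf4a in 7 of 17, among them the second deposited table and leaving out any of 4 arrays. Alb, the albumin gene, could not be assessed, since its only probe had a detection p under 0.05 on vehicle replicate 3 and tunicamycin replicate 3 alone.

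**Figure D1:**
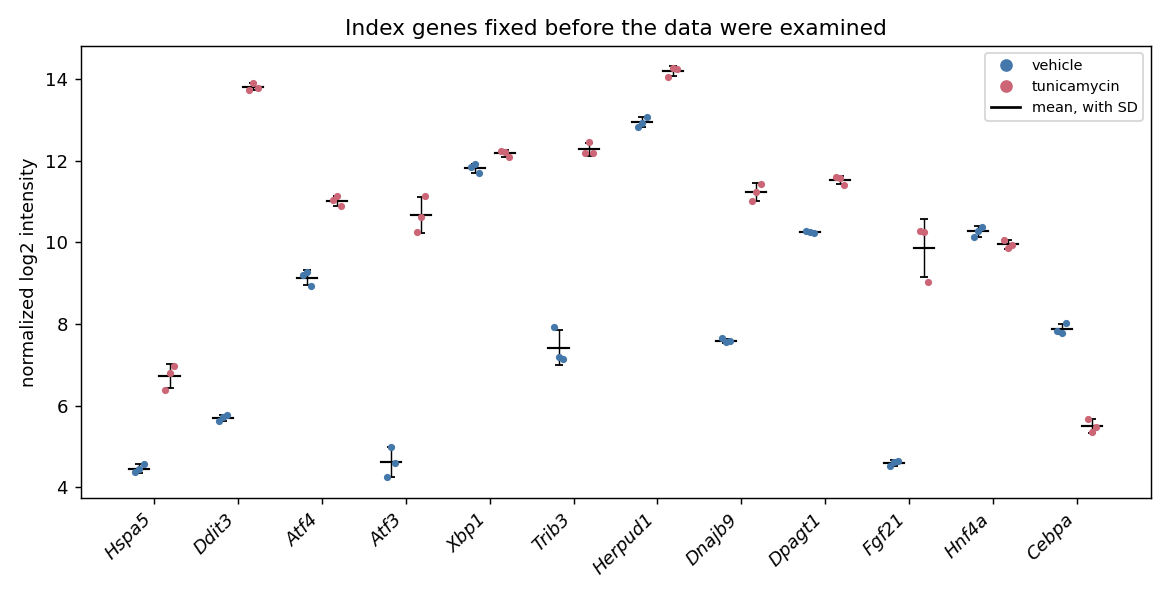
Normalized log2 intensity (vertical axis) of the 12 tested index genes on each array, in vehicle and tunicamycin samples, with the mean and SD of 3 arrays per group. Ddit3 lies near 5.70 in vehicle and 13.81 after tunicamycin, and Cebpa moves from 7.88 to 5.51.

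The largest rise over all named genes was in Nupr1, a stress-induced chromatin protein, which rose 278-fold (log2 fold change 8.12 ± 0.11, adjusted p = 4.10e-11), close to Ddit3. Derl3, which takes part in ER-associated degradation, was at least 169-fold higher, Psat1, an enzyme of serine synthesis, at least 62.6-fold, and Bhlha15, a transcription factor of secretory cells, at least 33.4-fold, none of them well above background on a vehicle array. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 45.4-fold, Aldh18a1, an enzyme of proline synthesis, 42.5-fold with detection on 1 of 3 vehicle arrays, and the receptor gene Tnfrsf12a 38.3-fold. Atf3 and Fgf21 completed the 10.

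The largest falls were in Keg1, at 178-fold (log2 fold change -7.48 ± 0.21, adjusted p = 5.17e-09), and Hsd3b5, a steroid dehydrogenase gene, at 86.7-fold. Depp1 fell 58.4-fold, with detection on 1 of 3 tunicamycin arrays, and Hes6, a transcriptional regulator, fell 50.0-fold. Hal, the first enzyme of histidine breakdown, fell 48.6-fold, and Acacb, an acetyl-CoA carboxylase, 38.9-fold. Igfals, which carries IGF in plasma, fell 36.2-fold, and Rgs16 35.2-fold. Gm4951 and Tmem25 fell 35.0-fold each by their brightest probe. The least changed probe had a log2 fold change of -0.64 for Gm4951 and -0.86 for Tmem25, and with the mean of a gene's probes the values were -2.89 and -2.36, so the size of these falls depends on the probe chosen. Without background correction the fold changes of 68 of 136 genes chosen for the text were smaller by more than 1.5 times, with a log2 fold change of 6.66 for Ddit3 and -5.63 for Keg1.

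Genes of ER protein folding rose together. Of 20 measured chaperones and folding enzymes, 18 rose and 0 fell (18 changed when adjusted over the list alone), with a median log2 fold change of 2.44 and a camera adjusted p of 4.70e-10. Creld2 rose 23.5-fold, Sdf2l1 14.6-fold and Hyou1 12.8-fold. Of 41 genes of ER translocation and vesicle transport, 35 rose and 1 fell (37 changed when adjusted over the list alone), with a median of 1.02 and an adjusted p of 4.70e-10. In that list Srprb, part of the receptor for the signal recognition particle, rose 10.9-fold, and Kdelr3, a receptor that returns ER proteins, was at least 8.89-fold higher. These lists were the only 2 of the 25 called that stayed past the threshold with an estimated correlation, each at an adjusted p of 0.0487.

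Targets of the PERK-ATF4-CHOP arm rose in 19 of 25 genes and fell in 2 (22 changed when adjusted over the list alone), with a median log2 fold change of 1.76, or 1.65 with undetected genes at their bound (adjusted p = 1.28e-06, and adjusted p = 0.0829 with an estimated correlation). Asns, Mthfd2 and Chac1 were among them, while Cth and Shmt2 fell. Of 22 genes of ER-associated degradation, 18 rose and 0 fell (19 rose and 1 fell when adjusted over the list alone). Their median was 1.15 (adjusted p = 1.28e-06, and adjusted p = 0.121 with an estimated correlation). Syvn1, an ER ubiquitin ligase, rose 10.3-fold and Selenos 6.64-fold. N-glycosylation genes rose in 26 of 33 and fell in 2 (28 changed when adjusted over the list alone), with a median of 0.94 (adjusted p = 2.51e-06, and adjusted p = 0.121 with an estimated correlation). Gfpt1, which supplies the sugar precursor, rose 15.5-fold by its brightest probe, while its 3 probes had log2 fold changes of 0.69 to 3.95 and their mean gave 1.88. Ddost and Alg2 rose 3.09-fold and 3.08-fold. Transcripts reported as cut by IRE1 fell in 9 of 12 genes and rose in 0 (9 changed when adjusted over the list alone), with a median of -1.0 (adjusted p = 0.00101, and adjusted p = 0.264 with an estimated correlation). Bloc1s1 fell 4.66-fold and Ces1d 7.83-fold.

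Genes that supply translation also rose. Aminoacyl-tRNA synthetases rose in 13 of 18 and fell in 1 (14 changed when adjusted over the list alone), with a median log2 fold change of 1.42 (adjusted p = 3.50e-05, and adjusted p = 0.133 with an estimated correlation). Wars rose 5.73-fold, Lars 4.05-fold and Rars 4.02-fold. Cytosolic ribosomal proteins rose in 26 of 29 and fell in 0 (28 changed when adjusted over the list alone), with a median of 0.53 (adjusted p = 2.40e-06, and adjusted p = 0.13 with an estimated correlation). Rps6 rose 1.85-fold and Rps7 1.77-fold, and Rplp0 rose 3.60-fold.

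Lipid synthesis genes fell. Of 23 genes of fatty acid and triglyceride synthesis, 21 fell and 2 rose (23 changed when adjusted over the list alone), with a median log2 fold change of -1.34 (adjusted p = 1.21e-06, and adjusted p = 0.121 with an estimated correlation). Besides Acacb, Acss2 fell 14.4-fold and Thrsp 14.2-fold, and Srebf1 fell too, while Dgat1 and Dgat2 rose. Of 18 genes of cholesterol synthesis and uptake, 13 fell and 4 rose (17 changed when adjusted over the list alone), with a median of -0.90 (adjusted p = 0.00519, and adjusted p = 0.156 with an estimated correlation). Dhcr7 fell 13.5-fold, Nsdhl 6.98-fold and Sc5d 5.35-fold, whereas Ebp, Fdps, Lss and Mvd rose. Fatty acid oxidation and ketogenesis fell in 18 of 25 and rose in 4 (22 changed when adjusted over the list alone), with a median of -0.62 (adjusted p = 0.00325, and adjusted p = 0.373 with an estimated correlation). Bdh1 fell 16.3-fold and Acaa1b 3.13-fold, and Acot2 was at least 4.79-fold higher by 1 of its 2 probes, a call that ended without any 1 of the 3 tunicamycin arrays, when the other probe represented the gene. Lipoprotein assembly and lipid droplet genes went both ways, 11 down and 6 up of 24 (17 changed when adjusted over the list alone), with a camera adjusted p of 0.172. There Apoa5 fell 14.8-fold, Apoc2 2.87-fold, and the droplet gene Cidec was at least 2.63-fold higher.

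Other hepatocyte functions were lower. Gluconeogenesis and glycogen genes fell in 12 of 16 and rose in 2 (14 changed when adjusted over the list alone), with a median log2 fold change of -1.19 (adjusted p = 0.000854, and adjusted p = 0.121 with an estimated correlation), including Gys2 at 5.59-fold, Slc2a2 at 4.22-fold and Pygl at 3.59-fold. Bile acid genes fell in 17 of 19 and rose in 2 (19 changed when adjusted over the list alone), with a median of -0.99 (adjusted p = 9.76e-05, and adjusted p = 0.265 with an estimated correlation). The sterol transporters Abcg8 and Abcg5 fell 28.2-fold and 21.5-fold, Abcg8 with detection on 1 of 3 tunicamycin arrays. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 23.8-fold with a wide SE of 0.71 on the log2 scale. Its log2 fold change of -4.57 became -5.44 without tunicamycin replicate 2 and -3.68 without replicate 3. Drug metabolism genes fell in 19 of 26 and rose in 2 (21 changed when adjusted over the list alone), with a median of -0.80 (adjusted p = 0.000339, and adjusted p = 0.156 with an estimated correlation). Cyp2b10 rose 30.5-fold by its brighter probe, with log2 fold changes of 4.93 and 0.96 for its 2 probes. Nr1i3, the nuclear receptor known to activate it, fell 8.77-fold and Fmo5 3.66-fold. Amino acid catabolism and urea cycle genes fell in 21 of 26 and rose in 0 (22 changed when adjusted over the list alone), with a median of -0.70 (adjusted p = 1.28e-06, and adjusted p = 0.125 with an estimated correlation), among them Hal, Bhmt at 6.58-fold and Hgd at 4.69-fold. Oxidative phosphorylation genes fell in 30 of 37 and rose in 1 (31 changed when adjusted over the list alone), with a median of -0.46 (adjusted p = 4.16e-05, and adjusted p = 0.265 with an estimated correlation). Cox6c fell 2.14-fold, a call that ended without a detection filter (adjusted p = 0.0549), and Atp5a1 2.0-fold by 1 of its 2 probes, while Cycs rose 2.24-fold by 2 of its 3 probes.

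Transcription factors of hepatocytes and plasma protein genes fell as well. Of 18 factors, 15 fell and 0 rose (15 changed when adjusted over the list alone), with a median log2 fold change of -0.79 (adjusted p = 0.000185, and adjusted p = 0.121 with an estimated correlation). Dbp fell 12.8-fold, Nr1i3 8.77-fold and Cebpa 5.17-fold. Plasma protein genes fell in 35 of 47 and rose in 1 (36 changed when adjusted over the list alone), with a median of -0.88 (adjusted p = 2.89e-07, and adjusted p = 0.143 with an estimated correlation). Igfals fell 36.2-fold, Serpind1, an inhibitor of thrombin, fell 6.69-fold, and Serpina7, which carries thyroid hormone, rose 7.79-fold. Genes of the periportal zone fell in 13 of 14 and rose in 0 (13 changed when adjusted over the list alone), with a median of -1.66, or -1.50 with undetected genes at their bound (adjusted p = 2.40e-06, and adjusted p = 0.0824 with an estimated correlation). Etnppl fell 15.3-fold and Cdh1 5.30-fold. Genes of the pericentral zone fell in 9 of 16 and rose in 1 (10 changed when adjusted over the list alone), with a median of -0.47 (adjusted p = 0.0162, and adjusted p = 0.373 with an estimated correlation). Slc1a4 rose 4.07-fold there. The difference between the zones was not tested. Some lists share members. Of the 14 periportal and 16 pericentral genes, 8 and 7 also stood in other lists. So did 5 of the 18 transcription factors and 6 of the 26 drug metabolism genes. The same held for 4 of the 12 transcripts reported as cut by IRE1 and 4 of the 25 PERK-ATF4-CHOP targets. It also held for 4 of the 19 bile acid genes and 5 of the 26 amino acid catabolism genes. These lists are therefore not separate evidence.

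**Figure D2:**
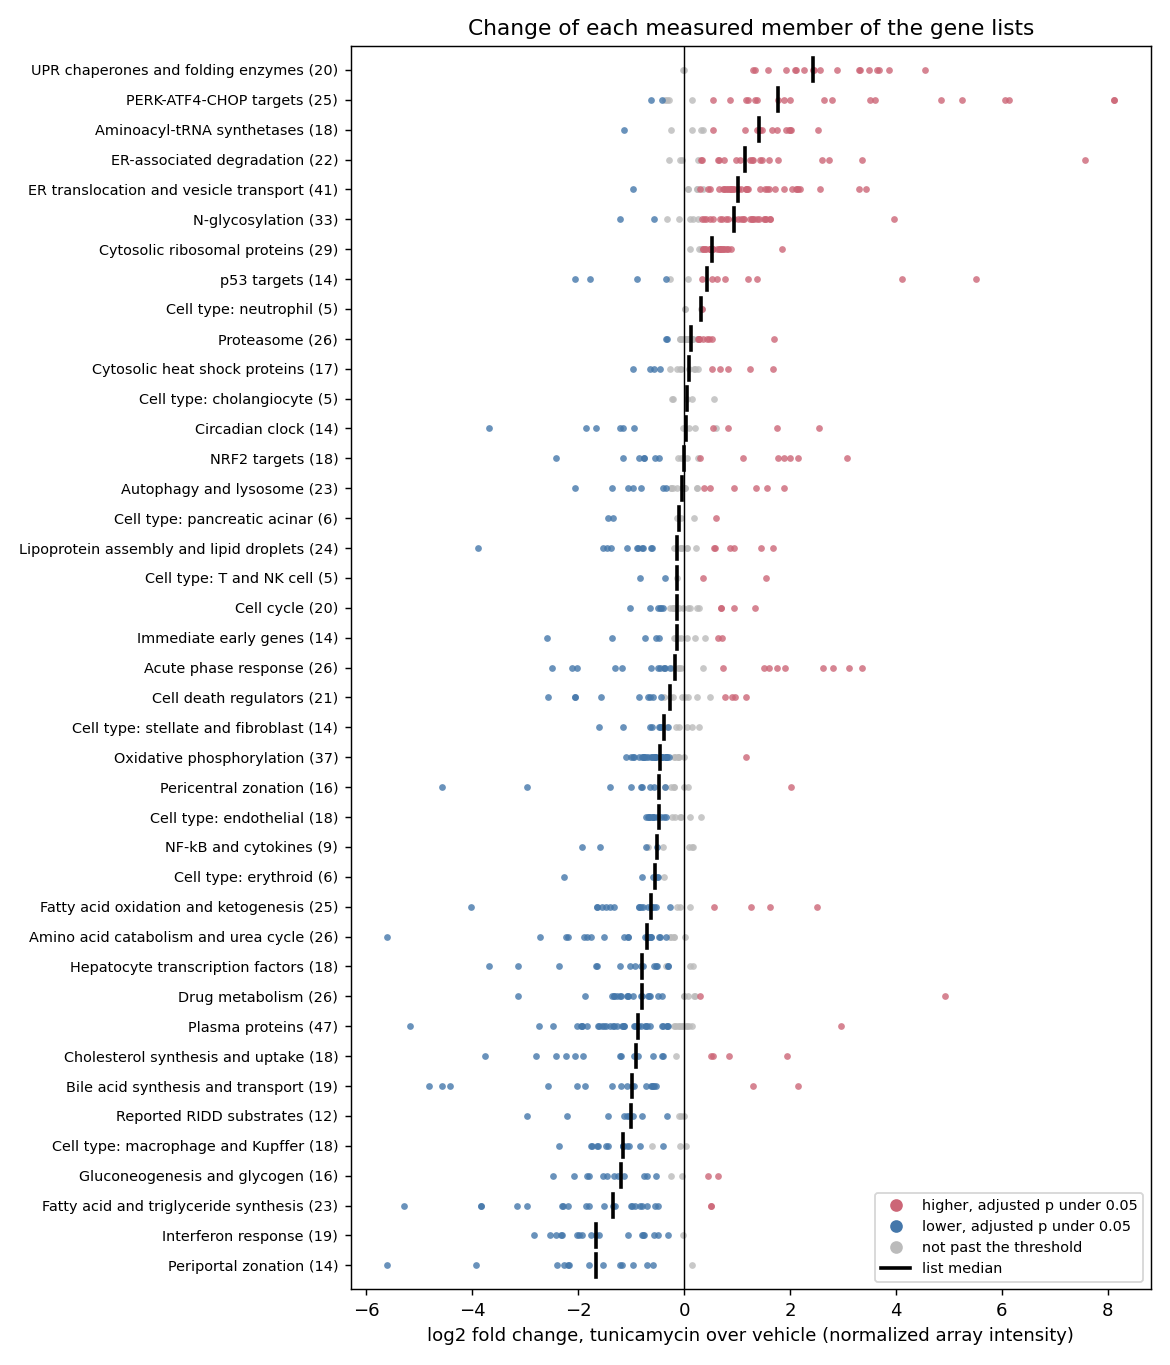
Log2 fold change of tunicamycin over vehicle (horizontal axis) for each measured member of the 41 tested gene lists, 1 point per gene with colour for the call at an adjusted p under 0.05, and a bar at each list's median. The number of measured genes stands in parentheses, and the medians run from 2.44 for ER chaperones to -1.66 for periportal genes.

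Interferon response genes were lower in tunicamycin livers. Of 19 genes, 18 fell and 0 rose (18 changed when adjusted over the list alone), with a median log2 fold change of -1.66 (adjusted p = 1.21e-06, and adjusted p = 0.121 with an estimated correlation). Igtp fell 7.15-fold, Usp18 5.82-fold and Ifit3 5.37-fold. The mean of the list on the 3 tunicamycin arrays was -1.49, -1.50 and -1.45 relative to vehicle.

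Markers of macrophages and Kupffer cells, the resident macrophages of liver, were lower to an unequal degree. Of 18 genes, 15 fell and 0 rose (15 changed when adjusted over the list alone), with a median of -1.15 (adjusted p = 0.000666, and adjusted p = 0.537 with an estimated correlation). Vsig4 fell 5.14-fold, Folr2 3.36-fold and C1qb 3.34-fold. The log2 fold change of Vsig4, -2.36, became -3.18 without tunicamycin replicate 3. The call of Vsig4 ended in 2 of 17 alternative settings, without a detection filter and with eBayes with trend and robust, at an adjusted p of up to 0.065. The list's mean was -1.54 and -1.36 on tunicamycin replicates 1 and 2 but -0.54 on replicate 3, and without replicate 3 its median was -1.39. Endothelial markers fell in 12 of 18 and rose in 0 (12 fell and 1 rose when adjusted over the list alone). Their median was -0.48 (adjusted p = 0.0182, and adjusted p = 0.447 with an estimated correlation). Eng, at 1.64-fold, and Stab2, at 1.61-fold, led the falls. Stellate cell and fibroblast markers fell in 8 of 14 and rose in 0 (8 changed when adjusted over the list alone), with a median of -0.38 (adjusted p = 0.0406, and adjusted p = 0.218 with an estimated correlation). Acta2 fell 3.04-fold by 2 of its 4 probes and Col4a1 2.24-fold. Erythroid markers fell in 5 of 6 (5 changed when adjusted over the list alone), with a median of -0.55 (adjusted p = 0.0406, and adjusted p = 0.467 with an estimated correlation), led by Alas2 at 4.81-fold. The stellate list was no longer called without tunicamycin replicate 2 (adjusted p = 0.0617) or with the mean of a gene's probes (0.111). The erythroid list was not called without vehicle replicate 2 (adjusted p = 0.0847), without tunicamycin replicate 1 (0.0776), without background correction or with a stricter detection filter.

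**Figure D3:**
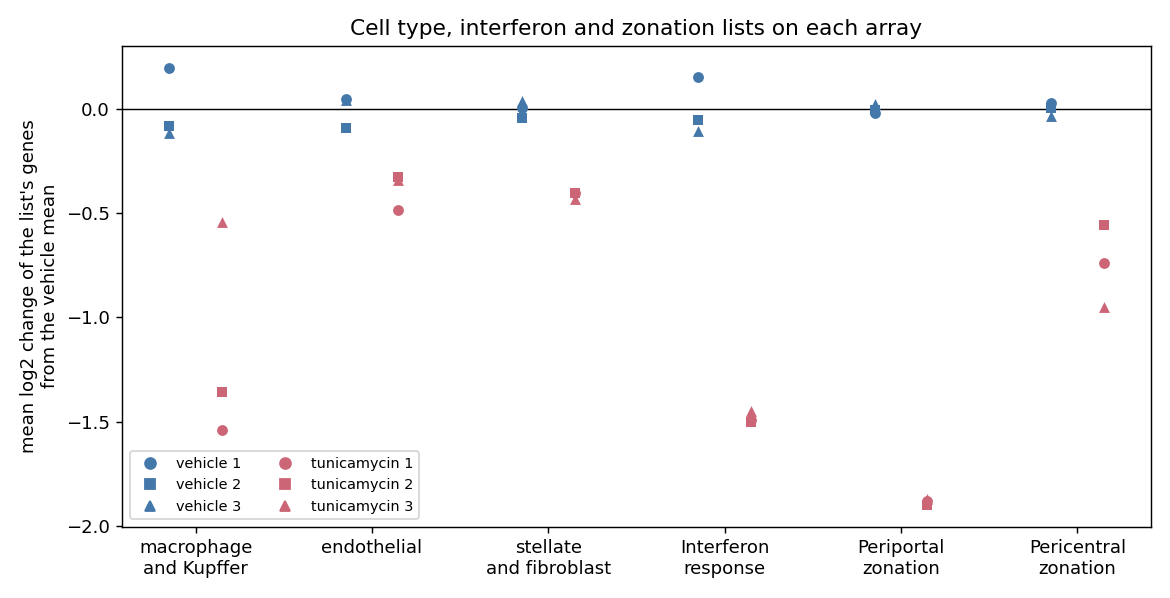
Mean log2 change from the vehicle mean (vertical axis) of the genes of 6 lists on each array, with colour for the group and marker shape for the replicate number. The macrophage list is at -1.54, -1.36 and -0.54 on the 3 tunicamycin arrays, and the interferon list at -1.49, -1.50 and -1.45.

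For other cell types few markers were measured. Neutrophil markers had 1 of 5 genes raised, Retnlg at 1.27-fold (0 changed when adjusted over the list alone, camera adjusted p = 0.668). That call ended in 7 of 16 alternative settings, among them leaving out vehicle replicate 2 or 3 or tunicamycin replicate 1 or 2, at an adjusted p of up to 0.208. None of 5 cholangiocyte markers passed, Krt23 having a log2 fold change of 0.57 ± 0.25 (0 changed when adjusted over the list alone, adjusted p = 0.93). Of 5 T and NK cell markers, 2 rose and 2 fell (4 changed when adjusted over the list alone, adjusted p = 0.809). The falls were in Ccl5, whose call ended in 6 of 17 alternative settings, and Thy1, in 5 of 13. Both calls ended without tunicamycin replicate 1 and without replicate 2. Cd8b1 rose 2.92-fold by the probe used, while its other probe fell. Of 6 pancreatic acinar markers, 1 rose and 2 fell (3 changed when adjusted over the list alone, adjusted p = 0.727), with Cela1 at 2.71-fold lower. The B cell list had 2 measured genes, of which Cd79b fell 1.74-fold, and the adipocyte list had 4, of which Car3 fell 5.89-fold (1 and 3 changed when adjusted over the list alone), so neither list was tested.

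The remaining lists of stress, inflammation and growth, given next, did not pass camera, though fry called some of them, as given below. Many of their members changed, but so did 62.4% of all items tested, so these counts alone do not set the lists apart. For p53 targets, 8 of 14 rose and 4 fell (12 changed when adjusted over the list alone, adjusted p = 0.267), with Cdkn1a and Gadd45a, at 17.3-fold, above and Bbc3, at 4.16-fold lower by 1 of its 3 probes, below. Cell death regulators had 4 raised and 9 lowered of 21 (13 changed when adjusted over the list alone, adjusted p = 0.265), where Bik fell 5.97-fold and Casp9 4.19-fold. Of 26 acute phase genes, 9 rose and 11 fell (20 changed when adjusted over the list alone, adjusted p = 0.93). Mt2, with detection on 1 of 3 vehicle arrays, rose 10.2-fold, Mt1 8.63-fold and Lcn2 7.04-fold, or by 2.23 instead of 2.82 on the log2 scale without vehicle replicate 3, while Crp fell. Of 9 NF-kB and cytokine genes, 0 rose and 4 fell (4 changed when adjusted over the list alone, adjusted p = 0.222), among them Nfkbia at 3.79-fold. Cxcl1 and Il1b also fell, but their calls ended in 7 and 4 of 17 alternative settings, both without vehicle replicate 2 among others. Of 18 NRF2 targets, 7 rose and 7 fell (14 changed when adjusted over the list alone, adjusted p = 0.987), with Srxn1 up 8.44-fold and Cbr1 down 5.32-fold.

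Immediate early genes had 2 raised and 5 lowered of 14 (6 changed when adjusted over the list alone, adjusted p = 0.572), with Dusp1 6.03-fold lower. Autophagy and lysosome genes had 6 raised and 7 lowered of 23 (13 changed when adjusted over the list alone, adjusted p = 0.93), including Sqstm1, 3.68-fold higher, and Ulk1, 4.18-fold lower. Proteasome genes had 8 raised and 2 lowered of 26 (6 changed when adjusted over the list alone, adjusted p = 0.191), led by Psmd8 at 3.23-fold. Cytosolic heat shock genes had 5 raised and 4 lowered of 17 (9 changed when adjusted over the list alone, adjusted p = 0.668), with Bag3 3.19-fold higher and Hspa1a at least 1.61-fold lower. Cell cycle genes had 4 raised and 6 lowered of 20 (10 changed when adjusted over the list alone, adjusted p = 0.771), with Ccne2 at least 2.07-fold higher. Of 14 clock genes, 4 rose and 6 fell (10 changed when adjusted over the list alone, adjusted p = 0.668), with Per1 5.85-fold higher, Dbp 12.8-fold lower and Nr1d1 at least 3.01-fold lower. The median and the mean of the acute phase, NRF2, clock and T and NK cell lists differ in sign.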

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

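The alternatives were chosen before the data were examined. Without background correction, 666 genes rose and 697 fell at least 2-fold, against 1288 and 1348, because the uncorrected background compresses folds. With an estimated correlation, limma's camera called 2 lists raised and 0 lowered, against 7 and 18 with the preset one. At an unadjusted p under 0.05 these were 7 and 7, and fry called 10 and 23. Beyond the calls of camera, fry called the p53 (fry adjusted p = 3.62e-05), proteasome (0.0133) and T and NK cell (0.04) lists raised. It called the lipoprotein and lipid droplet (0.00209), cell death (0.00257), clock (0.014), NF-kB (0.016) and immediate early (0.0166) lists lowered. Leaving out each array in turn gave 6467 to 7005 genes changed, 3143 to 3607 raised and 3161 to 3398 lowered, 1187 to 1308 raised and 1300 to 1383 lowered at least 2-fold, and 7 lists raised and 17 to 18 lowered. With the replicate number as a block, 7321 genes changed against 7291. The deviations of same-numbered arrays correlated at 0.116, 0.054 and 0.0029, and tunicamycin replicate 2 correlated better with vehicle replicate 3, at 0.071, so the numbers are not taken to pair the arrays. The chip as a block was not run, as no source used here gives the chip. Of 2283 alternative values for 136 named genes, 47 lost their call, in 11 genes that include Xbp1, Hnf4a and Acot2, 2 gained one, both Krt23, and 0 changed direction. A gene that no longer passed the detection filter gave no value and is not counted as lost. Derl3, Psat1 and Bhlha15, detected on the tunicamycin arrays alone, have values in 14 of 17 settings. Their rises could not be tested with a tunicamycin array left out. Dim probes limit the reading of Hspa5, Alb and genes below background.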

Other observations

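The tests in this part that were chosen only after the result was seen are the 5 added gene lists, the macrophage tests, the comparison of the interferon list with the macrophage list, the comparison of mean list changes between ways to normalize, and the test of food intake. The other normalization tests and the splits of the arrays were chosen before.

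Genes of ribosome biogenesis rose as a group, in 20 of 20 measured genes, with a median log2 fold change of 1.95 (camera adjusted p = 3.31e-10, and adjusted p = 0.192 with an estimated correlation). As the list was written after the results were seen, these p-values are not independent support. Nop56, a nucleolar protein, rose 11.9-fold, and Ncl, which encodes nucleolin, 8.56-fold. A list of enzymes of polyamine, proline and one-carbon synthesis had 10 measured genes. The values of at least 6, among them Psat1, Aldh18a1 and Srm, could be seen before it was written. Of the other 4, 2 rose and 2 fell, so no change of the group is claimed. Srm, the spermidine synthase, rose 21.2-fold and Mthfd2, a mitochondrial folate enzyme, 12.1-fold, while Shmt1 and Mthfd1, cytosolic folate enzymes, fell 5.35-fold and 4.81-fold.

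Genes with male-biased expression in mouse liver fell in 21 of 23 measured members and rose in 0. Keg1 and Hsd3b5, the 2 largest falls of all named genes, belong to this list and were seen before it was written. It was therefore tested without them and 8 other members that stood in earlier lists or among the genes chosen for the text. The values of all genes were on hand by then, so the members left are not known to be unseen. Of the 13 left, 12 fell and 0 rose, with a median of -1.25 (adjusted p = 3.14e-05, and adjusted p = 0.156 with an estimated correlation). The 13 include Selenbp2, which fell 13.1-fold. Of 29 female-biased genes only 4 were measured, of which 1 rose, Cyp2b10, and 2 fell. The sex of the mice is not given in the sources used here. A difference in sex between the groups was not tested, so these lists cannot be read as an effect of treatment alone.

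Macrophage markers fell on every tunicamycin array, least on replicate 3. A loss of non-parenchymal cells of every kind would lower macrophage and endothelial markers alike. On average the macrophage list fell further, by a difference of -0.76 ± 0.29 (SE). That difference was -1.06 and -1.03 on tunicamycin replicates 1 and 2 and only -0.20 on replicate 3, so it rests on the first pair. With 3 arrays per group and this spread, 2 standard errors is a loose bound, so a loss of every kind stays open. A weaker array or response in replicate 3 is argued against by the 24 other called lists. Their change there relative to the other tunicamycin arrays had a median ratio of 1.05 and a lowest of 0.826, against 0.375 for macrophages. These lists were chosen by their calls on the same arrays and some share members, so they are not independent. Before normalization, the median raw signal of tunicamycin replicate 3 was 96.8, the highest of the arrays. Fewer macrophages and lower expression of these genes in each cell both stay open, as neither was tested.

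The fall of interferon response genes may reflect fewer macrophages or lower interferon signalling. The interferon list fell further than the macrophage list by -0.33 ± 0.29 (SE), a difference within 2 standard errors, so the 2 cannot be told apart over the group. On tunicamycin replicate 3 alone the interferon list stood at -1.45 and the macrophage list at -0.54, and their change there divided by the mean change in replicates 1 and 2 was 0.97 and 0.375, but 1 array excludes nothing. The fall of the interferon list kept its direction under each way to normalize, in a comparison of means chosen after the result was seen. Its mean change of -1.48 was -1.51 with cyclic loess, -1.47 with 1 median per array and -1.39 with the second deposited table. The value closest to 0, without background correction, was -0.82 ± 0.05 (SE). That last setting keeps the quantile step and changes the background step. The list's median there, -0.72, missed the bound set in advance, so the planned test could not decide. It also shows that the size depends on the background correction. All these ways bring the arrays to a common level, so an error that they share could not be seen.

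The fall of fatty acid synthesis genes did not rest on the choice among the 5 ways to normalize. The median closest to 0 was -0.97, past the bound set in advance, and the mean change closest to 0 was -1.23 ± 0.07 (SE). An error shared by all 5 ways could not be seen here either. Lower food intake could also lower these genes, and food intake is not given in the sources used here. Genes that fasting raises in liver had a median of -0.62, with quartiles of -1.52 and 0.017, as 4 of 15, among them Pdk4 and Cyp4a14, rose and 11, among them Pck1 and Ppargc1a, fell. Camera placed this list lower, opposite to what fasting predicts (adjusted p = 0.049, and adjusted p = 0.304 with an estimated correlation), although 13 of the 15 also stood in lists or among genes seen before. As that call is lost with an estimated correlation and members went both ways, lower food intake stays open.

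The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7291 changed genes, 3621 raised and 3670 lowered, and 1288 and 1348 at least 2-fold. The highest of the other splits was 0 in each case, so 1 of 10 splits reached the real count. Every other split mixes vehicle and tunicamycin arrays, so the treatment difference widens the spread within its groups and hinders calls. A count of 0 there is thus no measure of chance. For lists, each other split was counted by the larger of its raised and lowered lists, since which group counts as treated is a choice. These splits still hold part of the treatment difference, so their list counts are no measure of chance either. With the real split included, 10 of 10 splits reached the 7 raised and 1 of 10, the real one, the 18 lowered, and the highest other was 17, a count of lowered lists. Counted by raised lists alone, the highest other was 10.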
